A study of Canis lupus familiaris with 20 samples.

How the data were processed

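Retinal RNA of 10 dogs was measured with a single array per eye, 20 arrays in all, in 4 groups of 5: PBS and CNTF eyes of normal dogs and PBS and CNTF eyes of CNGB3-mutant dogs. Per the labels' protocols, 12 µg CNTF went into right eyes and PBS into left eyes, retinas were taken after 1 week, and Cy3-labelled cRNA was made from 100 ng of RNA with an integrity number above 8. Sample labels give ages of 8.9 weeks for the normal dogs and 10.7 to 11.5 weeks for the mutants, while the study description gives about 11 months for both, so age was not used. Of the normal dogs 4 were carriers and 1, number 3, was homozygous wild type. Slides of 4 arrays each were read from the barcodes in the names of the array files, and the scan times in the file headers parted the arrays alike.

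The array files hold signal intensity per spot. Per the file headers, intensities came from Agilent Feature Extraction 9.5.3.1, which subtracted background and detrended each array, and were not scaled between arrays. The deposited matrix of all samples holds log2 values, and Partek 6.4 is named in the submitters' processing notes. Its scale was found from the data: all columns share the same distribution with a median of 6.18, as after quantile normalization, and slopes against log2 intensity are near 1. These deposited values were used only as an alternative. Saturation, background and outlier marks of each spot came from the array files. Probe positions refer to canFam2 per the file headers, and which exon or untranslated part a probe covers was not assigned here.

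Control spots (1417 per array) and spots marked as outliers were left out, and spots of the same probe were averaged, giving 43603 distinct probes. Log2 of the processed signal was taken and each array's 75th percentile over probes was subtracted. Probes were kept if well above background on at least 4 of 5 arrays of a group, which left 29545, of which 21400 were above background on all 20 arrays. Between 52.2 and 71.9% of probes were above background per array, and the 75th percentile lay between 292 and 594 intensity units. Probes with missing values were tested with at least 3 arrays per group. Gene names came from a table of gene names and synonyms of the assembly UU_Cfam_GSD_1.0. They were found by accession for 1667 probes, current symbol for 15924, gene number for 1828, description for 210 and synonym for 125, while 1327 kept the name in the file and 22522 had only a transcript identifier. Of the kept probes 16571 had a symbol, for 10407 genes. For a gene with several probes the probe with the highest mean signal was used.

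Tests used limma 3.58.1 in R 4.3.3, and figures Python 3.11.15 with matplotlib 3.10.9. For CNTF against PBS a linear model with the dog as a block and a CNTF term for each genotype was fitted to all arrays with empirical Bayes variances, two-sided, and the difference of the CNTF terms was tested in it. Genotypes were compared within PBS eyes and within CNTF eyes on 10 arrays each with no covariates. Benjamini-Hochberg adjustment was made over probes, and an adjusted p under 0.05 counted as a call. Both eyes of a dog were matched by replicate number, since number, sex, age and genotype match in the labels and both eyes came from each dog. As a check, the deviations of same-numbered arrays from their group means correlated at -0.15 to 0.69 over all probes, where 4 of 10 dogs matched best with their own number, and at 0.173 to 0.734 over the 500 most variable probes, where 9 of 10 did.

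Fixed gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 27 lists with at least 4 measured genes. Missing values were filled by group means for this test only. The lists were rod phototransduction, cone photoreceptor, outer segment structure, photoreceptor transcription factors, visual cycle, JAK-STAT and gp130, reactive gliosis, Müller glia, interferon response, antigen presentation, complement, microglia and macrophages, cytokines, chemokines and adhesion, neurotrophic and growth factors, MAPK and immediate early, unfolded protein response, apoptosis, crystallins, bipolar, amacrine, horizontal and ganglion cells, retinal pigment epithelium and melanocytes, endothelium and pericytes, glycolysis, cell cycle and ribbon synapse. Red cell and sex-linked genes were counted but not tested as sets. Genes named in the text are the 10 largest rises and 10 largest falls with a call and the same direction in all measured dogs (5 and 5 for the difference, and groups that do not overlap for the genotype comparisons), the first 4 members of each list in order of adjusted p, and targets of the study, among them CNTF, CNTFR, LIFR, STAT3, GFAP, CNGB3 and SAG. Some genes that meet this rule are not reported here. How many list members are printed, up to 4, was chosen after the values were seen. The lists, this rule, the design and the alternatives were fixed before the data were examined.

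A fold was not computed for a probe below background on all arrays of a group or saturated there, and a bound from the detection or saturation level is given instead. Slide was examined as a block without the dog and from the arrays of slide 3. Other alternatives were quantile normalization, normexp background correction with an offset of 50, the deposited values, other filters on dim probes, variance models and array weights, a fold threshold, 1 probe per gene, other blocks, leaving out each dog, sex, and for lists an estimated correlation and the fry test. Added after the data were seen were leaving out the dogs with dim arrays, array signal level as a covariate, and slide as a block for the lists.

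The programs were first tested on simulated data with the real arrays' spread, in which probes with an absolute log2 change of 1 were recovered in 59% of cases for CNTF in normal dogs, 61.2% in mutants, 38.4% for the difference, 54% between genotypes in PBS eyes and 50% in CNTF eyes. At a log2 of 2 the recovered shares were 95, 95, 88, 87.9 and 93.9% in that order. False calls among the 29545 probes were 5, 10, 8, 14 and 8. For lists in normal dogs, 2 of 2 changed lists and 1 other were called. Each probe was simulated on its own, with a dog effect but no slide, signal-level or between-probe structure. The false calls therefore do not measure how many the real arrays would give.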

Results

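Retinas of 10 dogs were compared a week after intravitreal injection of ciliary neurotrophic factor (CNTF), a cytokine that signals through gp130 receptors to STAT3, into the right eye and of buffer (PBS) into the left. In 5 dogs cone function was normal. The other 5 carried a missense mutation of CNGB3, which encodes the beta subunit of the cone cyclic nucleotide-gated channel and whose loss causes day blindness. Each retina was measured on its own single-colour array, 20 arrays on 5 slides. Of the normal dogs 4 carried a single copy of the mutation and all were male, while 3 of the mutants were female. Treatment followed slide closely. Only slide 3 held both treatments, with CNTF arrays of normal dogs 1 and 2 beside PBS arrays of mutant dogs 4 and 5, so the values within that slide compare treatment and genotype together. Values with slide as a block used no dog block and rest on few arrays. The PBS genotype difference is then that within slide 2, where PBS normal 5 is the only normal array. The CNTF change is the slide 3 difference plus that of slide 2 in normal dogs. In mutants it is the slide 3 difference plus that of slide 4, where CNTF mutant 1 is the only mutant array. Slide-block and slide 3 values are therefore not separate checks. Changes are given as log2 differences ± standard error (SE) with 5 dogs in each group, and genes were called at an adjusted p under 0.05. Unless stated, a named call had the same direction in all 5 dogs of its group. Where a probe was below background in every array of a group, or saturated there, its change is given as "at least" a fold, and where few arrays of a group were above background the size of a change is uncertain. On 27888 probes the first principal component held 46.7% of the variance and parted the CNTF arrays (scores 26.7 to 91.5) from the PBS arrays (scores -97.0 to 5.07).

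The first question was which retinal genes CNTF changed in dogs with normal cones. The largest rises were in acute-phase, complement and transport genes. FGG, the fibrinogen gamma chain, rose 256-fold (8.00 ± 0.40, n = 5 dogs, adjusted p = 2.19e-07), VMO1, a secreted protein of the vitelline membrane family, 196-fold (7.61 ± 0.36), and C3, the central complement component, 177-fold (7.47 ± 0.31, adjusted p = 9.45e-08). AQP3, a water and glycerol channel, rose 64.4-fold (6.01 ± 0.24) and DES, the muscle filament desmin, 51.1-fold (5.68 ± 0.50). DHX58, a sensor of viral RNA, rose 38.6-fold, above background on only 1 of the 5 PBS arrays (4 of 5 for DES). The chemokine CCL19 rose at least 73.6-fold, the glycoprotein CHI3L1 at least 50.7-fold and the dipeptidase DPEP1 at least 37.2-fold, with adjusted p of 8.24e-08 for CCL19 and 3.11e-07 for DPEP1. The FGG probe lay on chromosome 15 at 55282672 to 55282731 and the C3 probe on chromosome 20 at 56542868 to 56543122. With slide as a block the change was 8.66 ± 1.21 for FGG and 8.94 ± 0.73 for C3, and within slide 3 it was 6.95 and 7.24.

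The largest falls in normal dogs included a phospholipase receptor and a cone protein. PLA2R1, the receptor, fell 9.77-fold (-3.29 ± 0.18, adjusted p = 3.53e-07), IL5, an eosinophil cytokine, 9.52-fold (-3.25 ± 0.15), and ARR3, the cone arrestin, 8.51-fold (-3.09 ± 0.18, adjusted p = 5.5e-07). PTER fell 7.34-fold (-2.88 ± 0.13), NDUFA4L2, a mitochondrial protein induced by low oxygen, 6.97-fold (-2.80 ± 0.13) and FABP12, a fatty acid binding protein, 6.56-fold (-2.71 ± 0.16). HYAL4, a hyaluronidase relative, fell 8.35-fold, SEL1L2 7.78-fold and CYP26A1 7.37-fold. Of the CNTF arrays only 1 was above background for IL5, HYAL4, SEL1L2 and CYP26A1, and 3 were for PTER, so the sizes of these falls are uncertain. DPY19L2 fell at least 1.85-fold (adjusted p = 0.000357). The probe called CYP26A1 was placed by its gene number, while its description names subfamily C of the same P450 family. The ARR3 probe lay on chromosome X at 57655235 to 57656851. With slide as a block the change was -2.60 ± 0.70 for ARR3 and -3.44 for PLA2R1, and within slide 3 it was -2.93 and -3.18.

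Cone genes fell in normal dogs. Of 15 measured, 12 fell, 0 rose and 3 were not called. OPN1SW, the short-wavelength cone opsin, fell 4.70-fold (-2.23 ± 0.24), GNAT2, the cone transducin, changed by -1.82 ± 0.18 and PDE6H, a cone phosphodiesterase subunit, by -1.56 ± 0.11. The median change of the list was -0.83 (adjusted p = 2.99e-05, and 0.036 with an estimated correlation). It was -0.99 with slide as a block and -0.83 within slide 3. Of 18 rod phototransduction genes, 8 fell, 1 rose and 9 were not called. GUCA1A, a guanylate cyclase activator of photoreceptors, fell 5.67-fold (-2.50 ± 0.21), and CNGA1, the rod channel, 4.37-fold (-2.13 ± 0.31, in 4 dogs measured in both eyes). The rod transducin subunit GNGT1, saturated on all 5 PBS arrays, fell at least 1.54-fold (adjusted p = 0.00141), and phosducin, PDC, fell in 4 of 5 dogs (-1.18 ± 0.27). The rod list had a median of -0.37 and an adjusted p = 0.0102, adjusted p = 0.353 with an estimated correlation. Its median was -0.24 with slide as a block and -0.73 within slide 3. SAG, the rod arrestin, was saturated on all 20 arrays and yields no fold (adjusted p = 0.181).

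Other photoreceptor lists were mixed in normal dogs. Of 13 outer segment genes, 3 rose, 5 fell and 5 were not called (adjusted p = 0.141). ABCA4, the retinoid flippase, fell (-1.03 ± 0.10), as did EYS (-2.01 ± 0.24), while IMPG2, a matrix proteoglycan, rose (0.88 ± 0.10). Of 4 genes of the photoreceptor transcription factor list, 3 rose and 1 was not called (adjusted p = 0.195). NRL, which sets rod fate, had 0.66 ± 0.14 and OTX2 0.42 ± 0.13, and AIPL1, a phosphodiesterase chaperone and not a transcription factor, had 0.52 ± 0.14. The direction flipped within slide 3 for NRL (-0.03) and AIPL1 (-0.34). Of 13 visual cycle genes, 3 rose, 2 fell and 8 were not called, and 2 rose and 2 fell adjusted over the list alone. That list had a median of 0.03 and a mean of -0.05, which differ in sign (adjusted p = 0.953). The CNGB3 probe fell 2.50-fold (-1.32 ± 0.19, adjusted p = 0.000285), with -1.85 ± 0.39 with slide as a block and -0.83 within slide 3.

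Inner retinal neuron lists fell in part, and ganglion cell genes did not. Of 12 bipolar cell genes, 5 fell and 7 were not called, with 4 falling adjusted over the list alone. TRPM1, the channel of ON bipolar cells, fell (-1.002 ± 0.16), as did GRM6, their glutamate receptor (-0.71 ± 0.12, above background on 4 of 5 CNTF arrays). The list median was -0.25 (adjusted p = 0.0307, and adjusted p = 0.151 with an estimated correlation). Of 11 amacrine cell genes, 6 fell and 5 were not called, with 7 falling adjusted over the list alone. GAD1, which makes GABA, fell (-0.86 ± 0.11), as did PROX1 (-0.82 ± 0.10). The list median was -0.55 (adjusted p = 0.00272, and adjusted p = 0.0937 with an estimated correlation). Blocked by slide, neither list was called (adjusted p = 0.233 and 0.237), and the amacrine median flipped to 0.02. Of 11 ganglion cell genes, 5 rose, 1 fell and 5 were not called, with a median of 0.23 that flipped to -0.05 under quantile normalization and to -0.07 with the deposited values (adjusted p = 0.138). SNCG, gamma-synuclein, rose 9.39-fold (3.23 ± 0.15, in the 4 dogs measured in both eyes), GAP43, a growth-cone protein, 2.22-fold and THY1 2.16-fold.

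The gp130 pathway and reactive gliosis lists rose in normal dogs. STAT3, the main effector of CNTF, rose 4.53-fold (2.18 ± 0.12, adjusted p = 4.95e-07) and IRF1, an interferon regulatory factor, 3.89-fold (1.96 ± 0.17). Of 16 JAK-STAT genes, 6 rose, 1 fell and 9 were not called, with a median of 0.41 (adjusted p = 0.0315, and adjusted p = 0.289 with an estimated correlation). CNTF itself (0.36 ± 0.19), its receptor CNTFR (-0.22 ± 0.26) and LIFR (-0.17 ± 0.30) were not called (adjusted p = 0.125, 0.499 and 0.643), CNTFR being above background on 4 PBS and 2 CNTF arrays. Of 14 reactive gliosis genes, 12 rose, 0 fell and 2 were not called, with a median of 1.62 (adjusted p = 1.39e-06, and adjusted p = 0.122 with an estimated correlation). Besides CHI3L1, TIMP1, a protease inhibitor, rose 10.6-fold (3.40 ± 0.13), S100A6 9.02-fold (3.17 ± 0.21) and A2M, another protease inhibitor, 14.1-fold (3.82 ± 0.30). The glial filament GFAP rose 3.03-fold in all 5 dogs (1.60 ± 0.20, adjusted p = 0.000123), but was above background on only 3 PBS and 4 CNTF arrays. Its direction flipped within slide 3 (-0.16) and with slide as a block (-0.20 ± 0.84), a value that contains the slide 3 difference. Of 10 Müller glia genes, 7 rose, 1 fell and 2 were not called (adjusted p = 0.0538), with the mucin-like PDPN at 3.49-fold and the lipid carrier APOE at 3.45-fold.

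Immune lists rose in normal dogs. Of 18 antigen presentation genes, 17 rose and 1 was not called, with a median of 2.87 (adjusted p = 2.32e-13, and adjusted p = 0.0937 with an estimated correlation). The peptide transporter TAP1 rose 21.96-fold (4.46 ± 0.22; slide block 4.96 ± 0.58, within slide 3 3.93), PSMB8, an immunoproteasome subunit, 22.8-fold and the class I gene DLA88 12.4-fold. Of 20 interferon response genes, 17 rose and 3 were not called, with a median of 2.38 (adjusted p = 8.83e-09, and adjusted p = 0.0937 with an estimated correlation), among them IFI35 (11.3-fold), MX1 (15.2-fold) and IFI44L (13.2-fold). Of 15 microglia and macrophage genes, 15 rose, with a median of 2.66 (adjusted p = 9.33e-10, and adjusted p = 0.0937 with an estimated correlation). CSF1R, the growth factor receptor of microglia, rose 8.70-fold (3.12 ± 0.16), the adaptor TYROBP 18.2-fold (4.19 ± 0.24) and LAPTM5 19.3-fold (4.27 ± 0.28). Mean signal relative to the scaling level went from -1.62 to 2.57 for TYROBP and from -2.83 to 1.44 for LAPTM5. Of 14 complement genes, 10 rose, 1 fell and 3 were not called, with a median of 2.58 (adjusted p = 1.58e-06, and adjusted p = 0.0937 with an estimated correlation), and C1QA rose 14.6-fold, C1R 8.05-fold and C1S 6.94-fold. Of 15 cytokine, chemokine and adhesion genes, 9 rose, 1 fell and 5 were not called, with a median of 1.92 (adjusted p = 0.014, and adjusted p = 0.0937 with an estimated correlation). CCL5 rose 28.4-fold, with 1 of 5 PBS arrays above background, and ICAM1, a leukocyte adhesion protein, 3.77-fold.

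With bound members placed at their bound, the medians in normal dogs were 2.27 for interferon, 2.32 for complement, 2.36 for microglia and 1.33 for cytokine genes. With slide as a block the medians were 3.85 for antigen presentation, 2.54 for interferon, 2.98 for microglia, 2.47 for complement and 1.59 for cytokine genes. Within slide 3 they were 2.73, 2.61, 2.50, 2.04 and 1.35 in that order.

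Stress and growth lists had smaller medians than the immune lists in normal dogs, a comparison that was not tested. Of 20 unfolded protein response genes, 10 rose, 1 fell and 9 were not called, with ASNS, which makes asparagine, rising 4.27-fold (2.095 ± 0.15) and the chaperone PDIA4 by 1.02 ± 0.12. That list had a median of 0.55 (adjusted p = 0.0103, and adjusted p = 0.353 with an estimated correlation). Of 23 apoptosis genes, 12 rose, 3 fell and 8 were not called, with a median of 0.32 (adjusted p = 0.0498, and adjusted p = 0.151 with an estimated correlation). XIAP, a caspase inhibitor, fell 3.19-fold (-1.68 ± 0.11), while CASP4, an inflammatory caspase, rose 11.4-fold, with 3 of 5 PBS arrays above background, and BCL2 2.61-fold. Of 15 neurotrophic and growth factors, 5 rose, 4 fell and 6 were not called (adjusted p = 0.49), with NTF3, neurotrophin 3, rising 4.17-fold (2.06 ± 0.18) and the receptor GFRA1 by 0.99 ± 0.11. Of 18 MAPK and immediate early genes, 9 rose, 3 fell and 6 were not called (adjusted p = 0.0531), and MYC (4 of 5 PBS arrays above background) rose 4.47-fold and JUN by 1.09 ± 0.12.

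In normal dogs 15059 of 29336 probes passed in limma, 6875 higher and 8184 lower. Of these 3753 changed at least as far as a log2 of 1. With slide and dog both as blocks limma called 0 probes (4757 at unadjusted p under 0.05), and with slide alone 1147. Of 10759 probes called without the dogs of slide 3, 80.9% had the same sign within slide 3. With normexp background correction 5755 probes were called and 61.0% of them were higher, against 45.7% in the chosen fit.

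**Figure D1:**
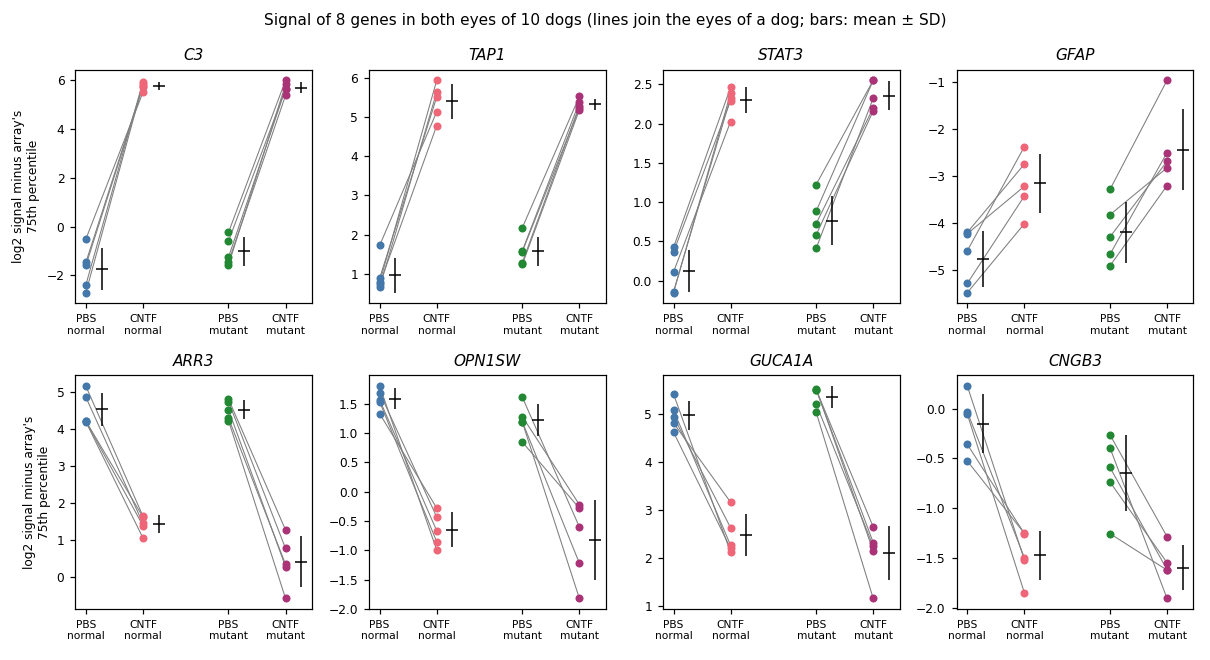
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 genes in the 4 groups, with a point per array, lines joining the eyes of a dog and bars for mean ± SD. C3 rose 177-fold in normal dogs, and GFAP rose but flipped to -0.20 with slide as a block.

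The second question was which genes CNTF changed in CNGB3-mutant dogs. The same acute-phase and complement genes led. FGG rose 155-fold (7.27 ± 0.40, n = 5 dogs, adjusted p = 5.62e-07), VMO1 150-fold (7.22 ± 0.36), C3 104-fold (6.70 ± 0.31, adjusted p = 2.24e-07) and AQP3 61.1-fold (5.93 ± 0.24). HP, the hemoglobin-binding haptoglobin, rose 38.2-fold (5.26 ± 0.25), with 2 of 5 PBS arrays above background. CHI3L1 rose at least 31.1-fold, CCL19 at least 28.7-fold, DPEP1 at least 25.6-fold and TLR1, a receptor for bacterial lipoproteins, at least 24.7-fold. With slide as a block the change was 7.69 for FGG and 7.12 ± 0.73 for C3.

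Among named genes with a computed fold, cone arrestin had the largest fall in mutants. ARR3 fell 17.1-fold (-4.09 ± 0.18, adjusted p = 1.91e-07), with -3.94 ± 0.70 with slide as a block. GUCA1A fell 9.57-fold (-3.26 ± 0.21), SLC14A1, a urea transporter, 9.49-fold (-3.25 ± 0.19) and PLA2R1 9.09-fold (-3.18 ± 0.18, with 4 of 5 CNTF arrays above background). STX1A, a synaptic membrane protein, fell 9.72-fold (-3.28 ± 0.31), with 1 of 5 CNTF arrays above background. NDUFA4L2 fell 7.44-fold, the immediate early gene EGR1 7.42-fold (-2.89 ± 0.19), the mitotic kinase CDK1 7.29-fold (-2.87 ± 0.17) and CCK, an amacrine cell peptide, 7.14-fold (-2.84 ± 0.14). ABCC11 fell at least 2.64-fold. The GUCA1A probe lay on chromosome 12 at 13799075 to 13799399.

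Rod and cone lists both fell in mutants. Of 18 genes of the rod phototransduction list, 13 fell, 0 rose and 5 were not called, with a median of -0.91 (adjusted p = 1.73e-07, and adjusted p = 0.0859 with an estimated correlation). It was -0.98 with slide as a block. Besides GUCA1A, GNB1, a transducin subunit, fell 2.40-fold (-1.26 ± 0.12) and PDE6G, a phosphodiesterase subunit, 2.21-fold (-1.14 ± 0.12). SAG, saturated throughout, yields no fold (adjusted p = 0.135). Of 15 cone genes, 12 fell, 2 rose and 1 was not called, with a median of -0.95 (adjusted p = 3.49e-05, and 0.0337 with an estimated correlation). KCNV2, a photoreceptor potassium channel subunit, fell 3.09-fold (-1.63 ± 0.14), OPN1SW 4.16-fold (-2.06 ± 0.24) and PDE6H 2.31-fold (-1.21 ± 0.11). The CNGB3 probe fell 1.93-fold (-0.95 ± 0.19, adjusted p = 0.00321, and -1.11 ± 0.39 with slide as a block). Of 13 outer segment genes, 3 rose, 6 fell and 4 were not called, with 8 falling adjusted over the list alone (adjusted p = 0.129), among them ABCA4 (-1.08 ± 0.10), while IMPG2 rose (1.16 ± 0.10). Of 13 visual cycle genes, 3 fell and 10 were not called, with the retinol dehydrogenase RDH8 3.47-fold and the opsin RGR 2.78-fold lower. That list had a median of -0.39 (adjusted p = 0.0407, and adjusted p = 0.586 with an estimated correlation). Of 4 genes of the photoreceptor transcription factor list, 1 rose, 1 fell and 2 were not called (adjusted p = 0.699).

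Inner retinal lists also fell in mutants. Of 12 bipolar genes, 6 fell and 6 were not called, with 7 falling adjusted over the list alone and a median of -0.40 (adjusted p = 0.017, and adjusted p = 0.0991 with an estimated correlation). GRM6 (-0.61 ± 0.12) and the kinase PRKCA (-0.64 ± 0.14) fell in this fit, but flipped to 0.13 and 0.32 with normexp, and were above background on 4 and 3 of the CNTF arrays. Of 11 amacrine genes, 6 fell, 1 rose and 4 were not called, with 9 falling and 1 rising adjusted over the list alone and a median of -0.60 (adjusted p = 0.00465, and adjusted p = 0.0859 with an estimated correlation). Blocked by slide, the values for the bipolar and amacrine lists were adjusted p = 0.49 and 0.306. In all, 3 list calls in mutants were lost with slide as a block, these among them. Of 11 ganglion cell genes, 4 rose, 2 fell and 5 were not called, with a median of 0.03 that flipped to -0.14 with normexp (adjusted p = 0.121), and SNCG rose 6.27-fold (2.65 ± 0.13).

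The gp130 pathway and reactive gliosis lists rose in mutants as well. STAT3 rose 3.02-fold (1.59 ± 0.12, adjusted p = 4.79e-06) and IRF1 4.12-fold (2.04 ± 0.17). Of 16 JAK-STAT genes, 5 rose, 1 fell and 10 were not called, with a median of 0.27 (adjusted p = 0.0339, and adjusted p = 0.255 with an estimated correlation). CNTF itself rose 1.69-fold (0.76 ± 0.19, adjusted p = 0.0108), while CNTFR (-0.39 ± 0.26, above background on 2 PBS arrays and 1 CNTF array) and LIFR (-0.09 ± 0.30) were not called. Of 14 gliosis genes, 10 rose and 4 were not called, with a median of 1.72 (adjusted p = 8.59e-07, and adjusted p = 0.097 with an estimated correlation), among them TIMP1 (9.41-fold) and A2M (13.0-fold). GFAP rose 3.39-fold (1.76 ± 0.20, adjusted p = 7.33e-05), above background on 2 PBS and 4 CNTF arrays, and flipped with slide as a block (-0.59 ± 0.84). Of 10 Müller glia genes, 3 rose, 2 fell and 5 were not called (adjusted p = 0.353), and GLUL, glutamine synthetase, fell 3.89-fold (-1.96 ± 0.21).

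Of 18 antigen presentation genes in mutants, 17 rose and 1 was not called, with a median of 2.49 (adjusted p = 9.51e-19, and 0.0462 with an estimated correlation), including PSMB8 (19.7-fold), TAP1 (13.6-fold) and DLA-12 (10.8-fold). Of 20 interferon genes, 17 rose and 3 were not called, with 18 rising adjusted over the list alone and a median of 2.27 (adjusted p = 6.81e-14, and 0.0338 with an estimated correlation), including IFI44L (15.8-fold) and MX1 (11.0-fold). Of 15 microglia genes, 14 rose and 1 was not called, with a median of 2.55 (adjusted p = 5.41e-14, and 0.0462 with an estimated correlation), including PTPRC, the leukocyte common antigen (10.2-fold), LYZ, lysozyme (8.12-fold), and CSF1R (5.87-fold). Of 14 complement genes, 12 rose and 2 were not called, with a median of 2.50 (adjusted p = 3.34e-11, and 0.0374 with an estimated correlation), including C1QA (9.77-fold) and C1S (5.49-fold). Of 15 cytokine genes, 9 rose, 1 fell and 5 were not called, with a median of 1.39 (adjusted p = 0.000167, and 0.0337 with an estimated correlation), CCL5 rising at least 4.93-fold. With bound members at their bound the medians were 2.05 for interferon, 2.02 for complement, 2.25 for microglia and 1.05 for cytokine genes.

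Trophic and stress genes in mutants included the neurotrophins. NTF3 rose 6.81-fold (2.77 ± 0.18) and BDNF (0.9998 ± 0.15). Of 15 neurotrophic factors, 6 rose, 1 fell and 8 were not called, with a median of 0.12 (adjusted p = 0.0489, and adjusted p = 0.0991 with an estimated correlation). Of 23 apoptosis genes, 6 rose, 1 fell and 16 were not called, with a median of 0.18 (adjusted p = 0.0154, and adjusted p = 0.0859 with an estimated correlation), and XIAP fell (-1.61 ± 0.11) while CASP4 rose 8.33-fold, with 4 of 5 PBS arrays above background. Of 20 unfolded protein response genes, 6 rose, 2 fell and 12 were not called, with 6 rising and 3 falling adjusted over the list alone (adjusted p = 0.0585). Of 18 MAPK genes, 5 rose, 2 fell and 11 were not called (adjusted p = 0.322).

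In mutants 8505 of 29336 probes passed in limma, 3399 higher and 5106 lower, and 2316 changed at least as far as a log2 of 1. With slide and dog both as blocks limma called 47 probes, and with slide alone 801. Of 3759 probes called without the dogs of slide 3, 94.2% had the same sign within slide 3. With normexp 3303 probes were called and 55.9% were higher, against 40.0%. The median change of all genes was -0.06 with 75th percentile scaling and 0.14 with normexp, and in normal dogs 0.00 and 0.12.

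**Figure D2:**
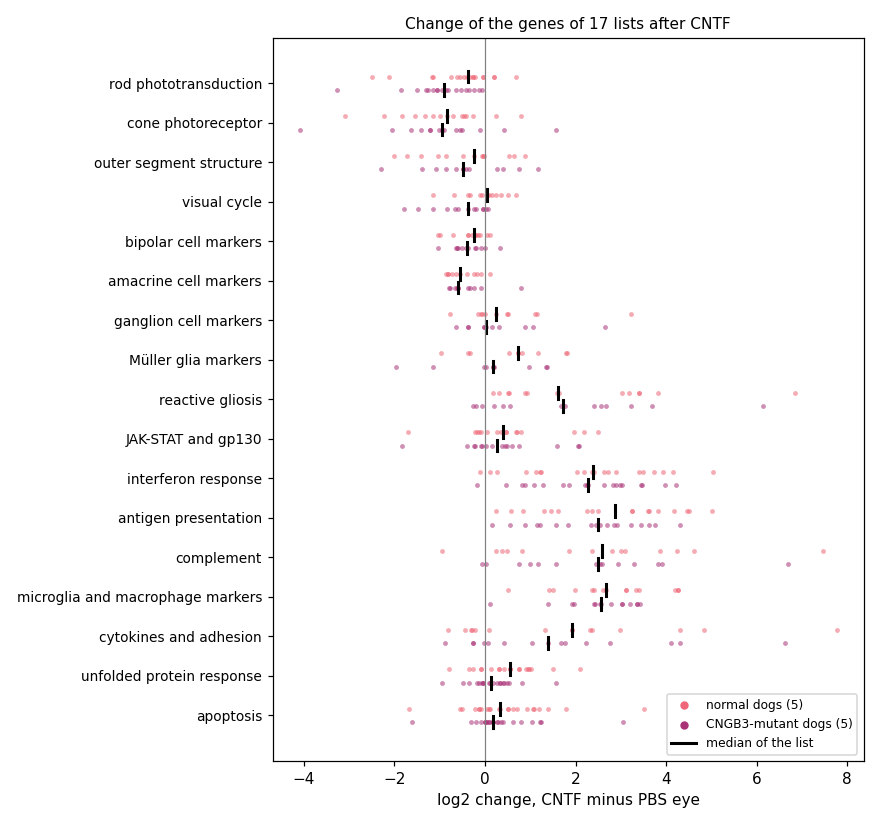
Log2 change, CNTF minus PBS eye (horizontal axis), of the genes of 17 lists in normal and mutant dogs, with a point per gene and a black bar at each list's median. Antigen presentation had medians of 2.87 and 2.49, and the ganglion cell median flipped to -0.05 in normal dogs under quantile normalization.

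The third question was whether CNTF acted differently in mutants. Of the called probes 5685 passed in both genotypes, with 2736 higher in both, 2914 lower in both and 35 opposite, while 9374 passed in normal dogs only and 2820 in mutants only. With independent lists 797 and 1424 would be higher and lower in both. The correlation of the changes over all probes was 0.764. These comparisons share no arrays but share a variance estimate. In both, treatment also followed slide closely, so slide could add to the overlap. Some genes of the rod list and others had more negative changes in mutants, although none passed (adjusted p = 0.104), and the cone list had a median difference of 0.18 (adjusted p = 0.681). The difference, mutant minus normal, was -0.86 ± 0.17 for GNB1, -0.68 ± 0.17 for PDE6G, -1.004 ± 0.25 for ARR3, -0.75 ± 0.22 for the long-wavelength opsin OPN1LW and -0.86 ± 0.20 for NRL. It was -1.66 ± 0.26 for EGR1, -0.75 ± 0.18 for MYC and 0.38 ± 0.26 for CNGB3 (adjusted p = 0.312), and the other targets given here lay between -0.59 (STAT3) and 0.40 (CNTF). Of 18 genes of the rod list, 0 were called, and 11 were lower adjusted over the list alone. The rod median was -0.50 (adjusted p = 0.0145, and adjusted p = 0.941 with an estimated correlation), and -0.21 under quantile normalization (adjusted p = 0.214). Blocked by slide, the rod list had an adjusted p = 0.303. Between genotypes the rod median was 0.39 in PBS eyes and -0.15 in CNTF eyes. The more negative rod difference thus came largely from the PBS arrays, and is not separate from the PBS comparison below. The median of all genes was -0.12. In limma 0 probes passed, with 10163 (34.6%) at unadjusted p under 0.05 and a smallest adjusted p of 0.104. With array weights 5183 passed, with slide as a block 69, and with slide and dog as blocks 45.

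The fourth question was how PBS eyes of mutants and normal dogs differed. With 1 probe per gene no gene was called (adjusted p = 0.0951 for the list members given here), and the groups also differ in sex and, per the sample labels, in age. The difference was 0.65 ± 0.13 for PDE6G, 0.59 ± 0.16 for GNB1, -0.87 ± 0.19 for GNAT2 and 0.68 ± 0.20 for OPN1LW. It was -4.15 ± 0.75 for CRYM, a thyroid hormone binding protein (-4.87 ± 1.61 with slide as a block), 1.55 ± 0.43 for the class II gene DLA-DQB1 and 0.91 ± 0.22 for PFKP, a glycolytic enzyme. The CNGB3 probe had -0.50 ± 0.20 (adjusted p = 0.122, and -1.02 ± 0.29 with slide as a block). The slide-block values of CRYM and CNGB3 compare the mutant arrays of slide 2 with PBS normal 5 alone. The mutation is missense, so the level of this probe checks nothing about genotype. The other targets given here lay between -0.34 (CNTFR) and 0.65 (STAT3). The rod list had a median of 0.39 (adjusted p = 0.0346), antigen presentation 0.56 (adjusted p = 0.0413) and glycolysis 0.43 (adjusted p = 0.0413). Each had an adjusted p = 0.853 with an estimated correlation. All 3 calls were also lost with quantile normalization and with the fry test, and 2 with slide as a block. Adjusted over the list alone 6 genes of the rod list and 8 of the antigen presentation list were higher. In limma 8 of 29433 probes passed, 3 higher and 5 lower, with 10191 (34.6%) at unadjusted p under 0.05. The count was 1 with quantile normalization, 6283 without normal dog 1 and 1 without each of normal dogs 3, 4 and 5. Named after the values were seen, the 8 probes included MAL, a myelin and lymphocyte protein (1.83 ± 0.25, adjusted p = 0.0475), CCSER2 (0.77 ± 0.10, adjusted p = 0.0475) and probes described as leucine rich repeat containing 17 (-1.46 ± 0.15, adjusted p = 0.0103) and S100A12 (-1.34 ± 0.16, adjusted p = 0.0401). For MAL and CCSER2 the gene's brightest probe was not called. The mean signals of the last 2 over all arrays, -5.35 and -4.46, lay below or within the range of the arrays' detection levels (-5.11 to -3.09). The sizes of their changes are therefore uncertain.

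The last question was how CNTF eyes differed between genotypes. None of the genes given here was called. The difference was -1.01 ± 0.29 for ARR3 (adjusted p = 0.644), -5.13 ± 0.84 for CRYM (adjusted p = 0.141), 1.34 ± 0.22 for TREM2, a microglial receptor (adjusted p = 0.153), -2.18 ± 0.53 for the pigment gene SLC45A2 (adjusted p = 0.5) and -0.57 ± 0.21 for the retinol saturase RETSAT (adjusted p = 0.764), which flipped to 0.16 with normexp. Of the normal and mutant arrays 4 and 5 were above background for TREM2, 4 and 2 for SLC45A2 and 5 and 4 for RETSAT. The CNGB3 probe had -0.12 ± 0.15, and the other targets given here lay between -0.51 (CNTFR) and 0.72 (GFAP). The visual cycle list had a median of -0.33 (adjusted p = 0.00178, and adjusted p = 0.537 with an estimated correlation). The retinal pigment epithelium list had -0.53 (adjusted p = 0.00178, and adjusted p = 0.537 with an estimated correlation), which flipped to 0.08 with normexp. The microglia list had a median of 0.09 and a mean of 0.23 (adjusted p = 0.0159, and adjusted p = 0.584 with an estimated correlation), its median flipping to -0.07 with slide as a block, and 3 of its genes were higher adjusted over the list alone. All 3 of these list calls were lost with slide as a block and with the fry test, and kept with quantile normalization. In limma 2 of 29360 probes passed, both lower, with 1641 (5.59%) at unadjusted p under 0.05, and 0 passed when any normal dog was left out. Named after the values were seen, one is described as the LDL receptor (-1.24 ± 0.14, adjusted p = 0.0348). Its mean signal over all arrays, -3.58, lay within the range of the arrays' detection levels (-5.11 to -3.09), so the size is uncertain.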

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

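The tests of slide, of slide 1, of array signal level and of dilution, with and without SNCG, below were chosen only after the results were seen.

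CNTF called 15059 probes in normal dogs, 51.3% of those tested, and 8505 in mutants. Of 100 splits drawn at random with the same group sizes only 1, the real one, gave as many in each genotype. The highest others gave 14235 in normal dogs (a split that separates the eyes of 3 dogs by treatment) and 1735 in mutants. Because the fit blocks by dog, only splits that part the eyes of every dog compare like with like. The 13 others of that kind in normal dogs gave at most 31 calls, and the 12 in mutants at most 13. That argues against chance, but so few splits cannot exclude it. On probes called without the dogs of slide 3, the difference of CNTF normal and PBS mutant arrays within slide 3 was 1.06 of that between other slides for calls in normal dogs (pairs 0.572 to 1.54) and 0.960 for calls in mutants (0.939 to 0.981), which argues against slide as the whole cause. With array signal level as a covariate 10707 and 9427 probes were called, which argues against signal level. With slide and dog as blocks 0 and 47 probes were called, while with slide alone C3 went from 7.47 ± 0.31 to 8.94 ± 0.73 in normal dogs and from 6.70 ± 0.31 to 7.12 ± 0.73 in mutants, the calls ending with the larger error. These slide-alone values contain the slide 3 difference and pass through PBS normal 5 or CNTF mutant 1, so they are no separate check. By the slide 3 arrays, slide stays open only for a part of the changes.

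Between genotypes in PBS eyes 10191 probes had an unadjusted p under 0.05 but only 8 were called, and for the difference of CNTF effects 10163 and 0. Leaving out single dogs moves the unadjusted count between 6382 and 12620 in PBS eyes and between 6157 and 11817 for the difference. These moves show how far the 2 counts rest on single dogs and do not test chance. Few splits reach the 2 counts. Of 100 splits, 3 gave as many at unadjusted p in PBS eyes (highest other 13532) and 2 for the difference (highest other 11712). By calls 2 did for the 8 in PBS eyes (highest other 9460) and 3 for the 2 in CNTF eyes (highest other 5712). All 100 reached the 0 calls of the difference (highest other 0), as every split must. The rule set beforehand took fewer than 5% of splits as against chance, and all these counts but the 0 met it. Other splits nevertheless gave more, and leaving out single dogs moves the 8 between 1 and 6283 and the 2 between 0 and 61. Chance was therefore not excluded for any of these counts. The split with 9460 calls exchanged PBS normal 1 with PBS mutant 5 and parts the arrays exactly by signal level, a structure of the samples, and over the 10 CNTF arrays signal level went along the PBS genotype direction within groups (r 0.792, permutation p = 0.0160), so it may be part of the pattern, and with it as a covariate 2257 probes had an unadjusted p under 0.05 (3259 with sex as a covariate, 5329 in males only) and for the difference 1691, where array weights gave 5183 calls. Sex, age, which was not tested, and genotype stay open, and slide 1 cannot be told apart from genotype, since only PBS normal 5 was on another slide, at 0.874 of the way from the mutants of slide 3 to slide 1 (mutants of slide 2 at -0.070 to 0.709).

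Cone genes fell in CNTF eyes while ganglion cell genes had means of 0.51 in normal dogs and 0.34 in mutants, or 0.24 and 0.10 without SNCG, and medians of 0.23 and 0.03 whose sign turned with other scalings. If RNA of immune or glial cells had diluted all neurons, cone and ganglion genes would move alike, provided that ganglion cell genes were not themselves regulated. Of 11 ganglion cell genes, 5 rose in normal dogs and 4 in mutants, which dilution would not give, so this condition was not met. Cone minus ganglion cell means were -1.47 in normal dogs (permutation p = 0.00055) and -1.29 in mutants (permutation p = 0.00466). Without SNCG they were -1.20 and -1.06 (permutation p = 0.00169 and 0.0132). The permutations exchanged genes between the lists and do not measure the spread between dogs. Amacrine medians were -0.55 in normal dogs and -0.60 in mutants and bipolar medians -0.25 and -0.40, falls that dilution would also give. Neither of those lists was called with slide as a block. Since ganglion cell genes rose in part, their values cannot decide whether dilution is the whole cause of the cone fall, a part of it or none. In normal dogs the rod and cone medians were -0.37 and -0.83 (-0.73 and -0.83 within slide 3), a difference that was not itself tested. With the 6 rod probes that saturated left out the rod median still lay 0.398 above the cone median, which argues against saturation as its whole cause. Loss of outer segments or a lower transcription in cones stays a hypothesis that was not tested.

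Some values lay far from the others of their group, 10 of 197 groups, and chance gives about 1 in 20. FGG rose by 6.11 in normal dog 4, against 8.17 to 9.004 in the other normal dogs. ABCA4 changed by -1.51 in mutant dog 4, against -1.04 to -0.92. STX1A changed by -5.09 in mutant dog 3, against -3.06 to -2.47. CRYM signal was 0.83 in PBS mutant 5 (others -3.45 to -2.29), 1.05 in CNTF normal 2 (others 3.45 to 3.87) and 1.22 in CNTF mutant 5 (others -3.31 to -2.57). DLA-DMA signal was -3.36 in PBS normal 3 (others -2.51 to -2.36) and -1.59 in PBS mutant 2 (others -1.98 to -1.88). DLA-DQB1 signal was 0.66 in PBS mutant 2 (others -0.66 to -0.32). PFKP signal was 3.19 in PBS normal 1 (others 2.34 to 2.59). The rod list stood out in a test of the difference of CNTF effects itself (adjusted p = 0.0145), with 0 of 18 members called, and the call was lost with an estimated correlation (adjusted p = 0.941), quantile normalization (adjusted p = 0.214) and slide as a block (adjusted p = 0.303).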

How the results depend on the processing

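The settings that leave out the dogs with dim arrays, that use array signal level as a covariate, and that block lists by slide were chosen after seeing the data. Where a result changed below, the cause was not tested, except that 1 probe per gene and a fold threshold count fewer probes.

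In normal dogs the 15059 calls became 5755 with normexp, 3753 at a log2 of at least 1, 5424 with 1 probe per gene, 0 with slide and the replicate block (4757 at unadjusted p under 0.05 in limma) and 1147 with slide and no replicate block. They ranged from 10980 to 14818 as each dog was left out. In mutants the 8505 became 3303, 2316, 3262, 47 and 801 in that order, and 5261 without the dogs with dim arrays, with 6402 to 7260 as each dog was left out. With no replicate block the counts were 11535 and 6698. The replicate block ended no other call of a count.

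The difference of CNTF effects had 0 calls, but 5183 with array weights, 7 with the replicate block as a random effect, 45 with slide and the replicate block, 69 with slide alone, 5 with slide as a random block and 1 without the dogs with dim arrays. Leaving out each dog gave 0 to 4, the 4 without mutant 1. With signal level as a covariate limma called 0 (1691 at unadjusted p under 0.05).

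Between genotypes in PBS eyes the 8 calls became 1 with quantile normalization, 2 with normexp, 1 with the deposited values, 4 with no filter, 3 with the strict filter, 5 with trend and robust variances, 5162 with array weights, 0 with 1 probe per gene (3719 at unadjusted p under 0.05 in limma), 2 with slide as a block, 9678 with slide as a random block and 147 with the replicate block as a random effect. They were 4 with sex as a covariate, 30 in males, where the 2 male mutants were compared, 1 without the wild-type dog, 0 without the dogs with dim arrays (5744 at unadjusted p under 0.05) and 1 with signal level as a covariate. Leaving out each dog gave 1 to 6283: 6283 without normal 1, 3 without normal 2, 1 without each of normal 3, 4 and 5, 16 without mutant 1, 5 without mutant 2 and 41 without mutant 5.

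In CNTF eyes the 2 calls became 0 with quantile normalization, normexp, the deposited values, no filter, the strict filter or without the wild-type dog (in limma 1676, 781, 1720, 1672, 1094 and 1225 at unadjusted p under 0.05). They were 1 with trend and robust variances, 1 probe per gene or sex as a covariate, 6 with array weights, 190 with slide as a block, 28 with slide as a random block, 22 with the replicate block as a random effect, 5 in males, 10 without the dogs with dim arrays and 4 with signal level as a covariate. Leaving out each dog gave 0 to 61: 0 without each normal dog, 61 without mutant 1, 1 without mutant 4 and 7 without mutant 5.

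The 27 list calls for CNTF became 7 with an estimated correlation. They were 39 with fry, 29 with quantile normalization, 27 with no replicate block, 24 with slide and the replicate block and 31 with slide alone, and none reversed. Of the called genes that meet the naming rule, 75 of 75 in normal dogs and 65 of 66 in mutants lost the call with slide and the replicate block, and 23 and 28 with slide alone. With both blocks the median size of their changes was 2.71 in normal dogs and 2.62 in mutants, against 2.71 and 2.802, while the median SE grew from 0.17 to 0.61 and from 0.18 to 0.64.

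The SAG probe, saturated on all arrays, has no readable direction, and its values were -0.0567 with quantile normalization and -0.0564 with the deposited values in normal dogs and 0.0387 with slide alone in mutants. In normal dogs the sign turned for CNTFR (0.22 with normexp, and -0.39 to 0.11 as each dog was left out, the highest without normal 1), GFAP (-0.20 with slide alone) and LIFR (-0.46 to 0.0498 as each dog was left out, the highest without normal 2, and 0.0498 without the dogs with dim arrays). In mutants it turned with normexp for CNTFR (0.54), GRM6 (0.13) and PRKCA (0.32), with slide alone for GFAP (-0.59), and without mutant 4 for LIFR (-0.23 to 0.22 as each dog was left out). The difference for CNGB3 was -0.19 with signal level as a covariate. In CNTF eyes normexp turned CNGB3 (0.14), MLANA (0.54) and RETSAT (0.16), and CNGB3 was 0.0217 without the dogs with dim arrays. Genes on few arrays above background, GFAP, CNTFR and MLANA among them, are limited by signal.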

Other observations

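Lists with smaller or mixed changes held some large single genes. CDK1, the mitotic kinase, fell with CNTF in normal dogs (-2.66, adjusted p = 1.1e-06) as in mutants, while MCM6, a replication helicase, rose (1.36 and 1.11) and so did the cell cycle inhibitor CDKN1A (1.98 and 1.22). Of 14 cell cycle genes 7 rose, 1 fell and 6 were not called in normal dogs, and 5 rose, 2 fell and 7 were not called in mutants (adjusted p = 0.201 and 0.157). Of 12 endothelial and pericyte genes 6 rose, 2 fell and 4 were not called, and 3 rose, 2 fell and 7 were not called in mutants (adjusted p = 0.332 and 0.408). Besides DES, the endothelial glycoprotein EMCN rose (1.32 and 1.42, with 4 of 5 mutant PBS arrays above background), and the VEGF receptor KDR fell (-0.78 and -1.21). Of 19 glycolysis genes 5 rose, 3 fell and 11 were not called, and 3 rose, 5 fell and 11 were not called in mutants (adjusted p = 0.384 and 0.33), with LDHA rising (0.71 and 0.51) and the lactate transporter SLC16A1 falling (-0.37 and -0.88).

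Of 13 ribbon synapse genes 3 rose, 3 fell and 7 were not called in normal dogs, and 2 rose, 5 fell and 6 were not called in mutants (adjusted p = 0.742 and 0.0612). The complexins of photoreceptor and amacrine synapses moved apart, with CPLX4 falling (-1.09 and -1.37) and CPLX3 rising (1.35 and 0.65). Of 11 pigment epithelium and melanocyte genes 3 fell and 8 were not called in each genotype (adjusted p = 0.141 and 0.0744), among them the melanosome protein PMEL (-0.49 and -0.60), and the list median in mutants of -0.60 flipped to 0.11 with normexp. Adjusted over that list alone, 1 fell in normal dogs and 3 in mutants. Of 4 horizontal cell genes 1 rose, 2 fell and 1 was not called, and 1 fell and 3 were not called in mutants, with ONECUT2 falling (-0.80 and -0.63, on 3 of 5 mutant CNTF arrays above background; adjusted p of the list = 0.865 and 0.77). Of 10 crystallin genes 1 rose, 1 fell and 8 were not called in normal dogs, with CRYGA at 1.42 and CRYBA2 at -0.83, and 2 rose and 8 were not called in mutants (adjusted p = 0.865 and 0.999). In mutants 0 crystallin genes rose adjusted over the list alone. The hemoglobin gene HBD, the only red cell gene measured, had 0.59 and -0.02 and was not called. Of 4 sex-linked genes 2 fell in normal dogs and 1 in mutants.

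The Y-linked gene KDM5D had a log2 signal of 0.39 to 0.75 on the arrays of male dogs and of -2.19 to -1.16 on the 6 arrays of females. CRYM signal was low in 4 of the 5 mutants in both eyes, and mutant 5 had 0.83 and 1.22. No arrays were identical, with a highest correlation of 0.990.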
